A study of Arabidopsis thaliana with 21 samples.

How the data were processed

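The series follows Arabidopsis thaliana, cultivar Col-0, through the change from a dry seed to a seedling. Per the labels, seeds lay for 72 h at 4 °C in the cold on wet filter paper and were then moved to constant white light at 22 °C. At each of the 7 stages 3000 seeds or seedlings were picked under a stereomicroscope, and the 3 replicates of a stage were biological, each from seeds pooled over 3 to 4 plants. RNA was extracted with a hot borate protocol, and 50 ng of it was amplified and labelled with biotin. The sources used here do not name the array platform, the annotation release behind its probe sets or what the 6 h of imbibition counts from.

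The deposited values are on the log2 scale. The submitters' processing notes name RMA, which corrects background, normalizes arrays by quantiles and summarises probes to 1 value per probe set, and the version of its software is not given in the sources used here. The table held 35986 probe sets named by transcript model for 21 arrays, with values from 1.49 to 12.86, and all of its sample columns were used. Probe sets of 1 locus were averaged, which joined several probe sets for 5818 loci. The 215 probe sets shared between loci were left out, which lost 192 loci and left 27789 genes. Values of close paralogs can still share signal, since probe sequences were not used here. Gene names came from the reference table for assembly TAIR10.1, which held 27175 of the loci and gave 10537 of them a symbol. A gene without a symbol is given by its locus, names in brackets after a symbol are synonyms, and no coordinates are given, since the build of the probe sets is not stated.

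All 21 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with a mean per stage and 14 residual degrees of freedom, followed by moderation of the variances with the default settings. Each of the 6 consecutive steps and the span from DS to OC was a contrast, later stage minus earlier stage, tested 2-sided. A gene was counted as changed at a Benjamini-Hochberg adjusted p under 0.05 within the comparison and a log2 change of at least 1. Limma's F test over the 6 steps was used for change across the series, with a range of stage means of at least 1. The stage with the highest mean was counted for genes that passed it. Distances between stages were 1 minus the Pearson correlation of stage means across genes.

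The lists hold 20 groups of genes: storage proteins, LEA proteins, oil body proteins, heat shock proteins, maturation and dormancy regulators, abscisic acid, gibberellin, expansins with XTHs and mannanases, beta-oxidation with the glyoxylate cycle, ribosome and nucleolus, cell cycle and replication, photosynthesis, chlorophyll biosynthesis, root hair formation, light signalling and clock, auxin transport and root meristem, HD-Zip class I factors, Polycomb and repressors of embryonic traits, endosperm markers and seed coat markers. A further list of reference genes served only for an alternative centring, and its 9 measured members had median levels of 7.5 at DS, 7.96 at 6H and 7.38 at OC. Of 368 members of the 20 lists 363 were measured. CLO2, RPL9D and BMI1B, and SAND among the reference genes, were left out because the reference table gives their loci another name, and HSD1 and the HD-Zip gene HB1 because no probe set measured them alone. Members that rose or fell were counted at an adjusted p under 0.05 over all genes and, beside it, adjusted over the list alone. Each list was tested against all other genes with camera at a preset correlation of 0.01, with adjustment over all 140 tests. Camera with an estimated correlation (statmod 1.5.0) and fry, which tests whether members move on balance one way without a comparison with other genes, were run beside it.

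Genes were named by a fixed rule. It took the 6 largest rises and falls of a step (10 and 10 from DS to OC) among changed genes whose 3 arrays lay beyond the 3 of the other stage. In each list it took the 3 largest rises and falls that passed and the 2 largest changes that did not. For each stage it took the 5 genes with the largest gap to the next highest stage, and it added 17 genes named for every comparison.

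The lists, the rule, the comparisons, the thresholds and all alternatives but the last named here were set before the data were examined. The alternatives were a further quantile normalization, centring of arrays on the median of all genes or on the reference genes, omission of dim genes (fewer than 3 arrays above the 30th percentile), a trended and robust variance prior, array weights, the probe set with the highest mean in place of the average. Further ones were limma's treat, other fold and range thresholds, a fit on the 6 arrays of a comparison, Spearman correlation, camera on ranks, a replicate term and omission of each array in turn. Omission of DS replicate 2 and OC replicate 2 together and omission of genes near the floor were chosen after the data were seen.

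The pipeline was tested on simulated data. With noise of each gene's own spread and 100 genes shifted, a log2 change of 1 was found at the adjusted p for 87% of genes in a simulated DS to 6H step and 84% in a TR to RP one, and a change of 2 for 99% and 100%. With the threshold of 1 on the log2 change as well, 43 and 45 of the 100 genes with a change of 1 were found, and 99 and 100 with a change of 2. There were 11 and 14 false calls at the adjusted p and 0 with both thresholds. A list shifted by 0.5 passed both of its tests, with 0 and 3 false calls among the other tests. Correlation between genes was not simulated, so real false list calls can differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.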

Results

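Transcript abundance was measured on 21 expression arrays in Arabidopsis thaliana, cultivar Col-0, from the mature dry seed to the seedling with opened cotyledons. The 7 stages were dry seed (DS), seed imbibed for 6 h (6H), rupture of the seed coat or testa (TR), protrusion of the radicle (RP), formation of root hairs (RH), greening of the cotyledons (GC) and opening of the cotyledons (OC). Each stage had 3 biological replicates, each a pool of seeds from several plants, and the number of arrays limits the precision of every value. The values covered 27789 genes and ran from 1.49 to 12.86 on the log2 scale. The lowest Pearson correlation across genes between 2 replicates of a stage was 0.981, where genes are not independent replicates. In what follows a change is a difference of stage means on the log2 scale ± its standard error from limma, with n = 3 per stage, and a level is a stage mean. A level under 3.47, the 30th percentile of all values, was taken as near the signal floor. A change from or to such a level is to be read as a lower bound, and its rank among the largest as uncertain. This held for 41 of the 92 largest rises and falls over the 7 comparisons. A member of a gene list that rose or fell did so at an adjusted p under 0.05 over all genes.

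Across the 7 stages 18463 genes, 66.4% of those measured, changed by limma's F test with a range of at least 1. Among them 5235 genes (28.4%) were highest in dry seed, 3809 (20.6%) at 6 h and 4114 (22.3%) in seedlings with opened cotyledons. The stages between held fewer maxima: 1548 at testa rupture, 1053 at radicle protrusion, 1273 at root hair formation and 1431 at greening. On median-centred arrays 9970 genes were highest in dry seed, and on arrays centred on reference genes 2120 were highest at 6 h, 603 at radicle protrusion and 6233 with opened cotyledons. The largest gaps above every other stage belonged at DS to AT4G11911 (level 9.22, gap 5.82), the sugar transporter gene SWEET6 (AT1G66770, level 8.93, gap 5.65) and the heat shock factor gene HSFA9 (AT5G54070, level 9.47, gap 5.49). At 6H they belonged to IAA33 (AT5G57420, level 7.38, gap 3.14) and the metallothionein gene MT1B (AT5G56795, level 9.76, gap 2.98). They belonged at TR to AT2G43860 (6.76, gap 2.42), at RP to AT2G27140 (8.26, gap 2.05), at RH to AT2G05910 (8.61, gap 2.73) and at GC to AT3G42725 (7.42, gap 2.99). At OC the largest gaps were those of AT1G55990 (level 10.08, gap 6.76), AT3G53980 (9.19, gap 6.52) and PELPK2 (AT5G09520, 9.33, gap 6.1).

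The distance between consecutive stages, as 1 minus the Pearson correlation of stage means across genes, was 0.113 from DS to 6H and 0.0792 from 6H to TR. It was 0.0167 from TR to RP, 0.0311 from RP to RH, 0.0196 from RH to GC and 0.0442 from GC to OC. Each of these lay above the mean distance between replicates of the stages compared, which ran from 0.00665 to 0.0124 over the 6 steps. The first principal component held 60.6% of the variance and the second 23.3%.

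**Figure D1:**
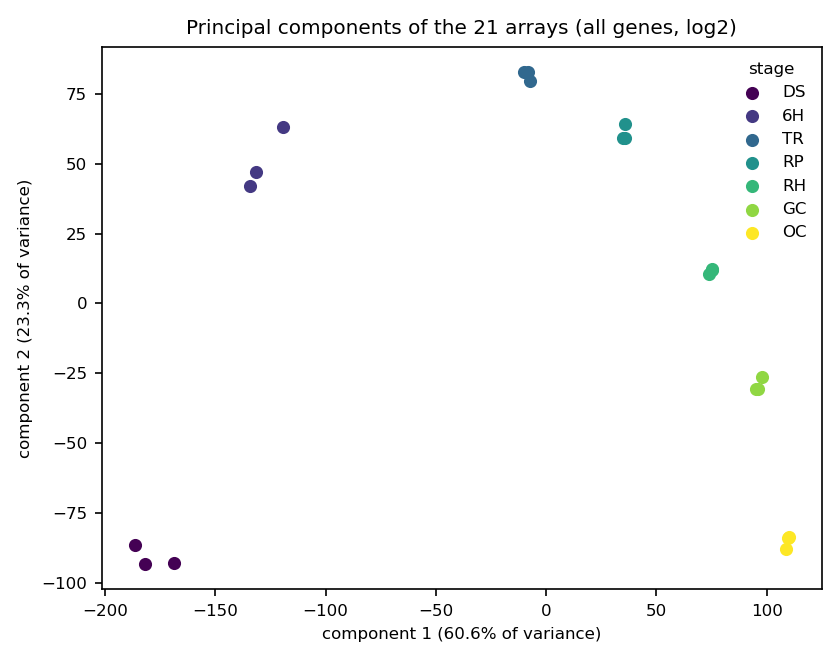
Scores of the 21 arrays on the first 2 principal components, which hold 60.6% and 23.3% of the variance over genes; each point is 1 array, coloured by stage, with 3 arrays per stage. Arrays of a stage lie together, and DS and 6H lie apart from the later stages.

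**Figure D2:**
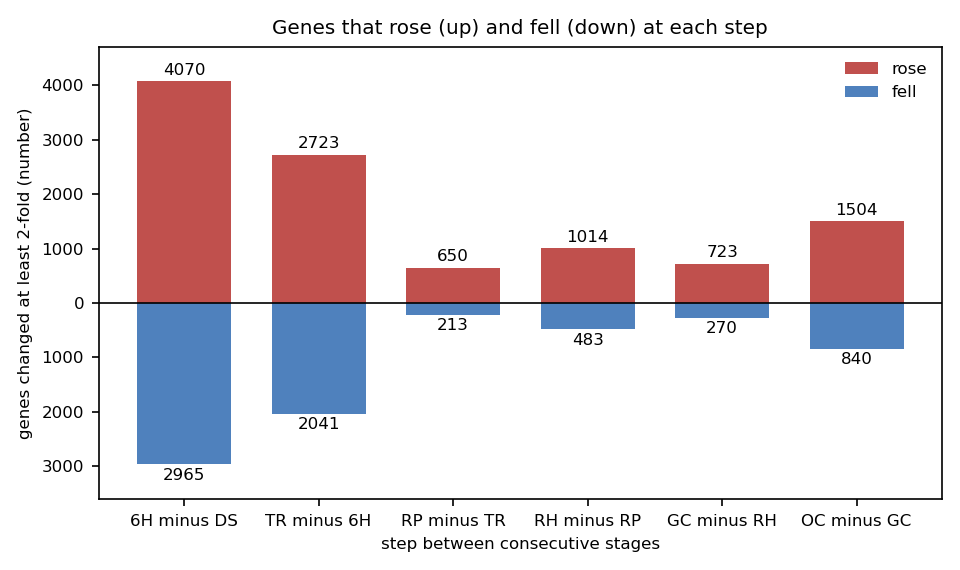
Genes that rose or fell in each of the 6 consecutive steps (adjusted p under 0.05 and a change of at least 2-fold). Bars start at 0 and count genes. The step from DS to 6H has 4070 genes up and 2965 down, and the step from TR to RP has 650 up and 213 down.

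The 20 gene lists had their highest median levels at different stages. The median level of the storage protein list was 11.66 ± 0.12 (SD, n = 3) in dry seed, 10.78 at 6H and 6.29 at TR, and that of the LEA list was 11.09, 9.67 and 6.9 at the same stages. The expansin, XTH and mannanase list stood at 4.23 ± 0.37 (SD) in dry seed and 8.49 ± 0.09 (SD) at TR. The cell cycle list had its highest median at GC (6.84 ± 0.15 SD), and the root hair list stood at 3.74 ± 0.25 (SD) at RP and 7.32 ± 0.12 (SD) at RH. The photosynthesis list stood at 4.68 ± 0.25 (SD) at 6H and 10.57 ± 0.05 (SD) at OC.

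**Figure D3:**
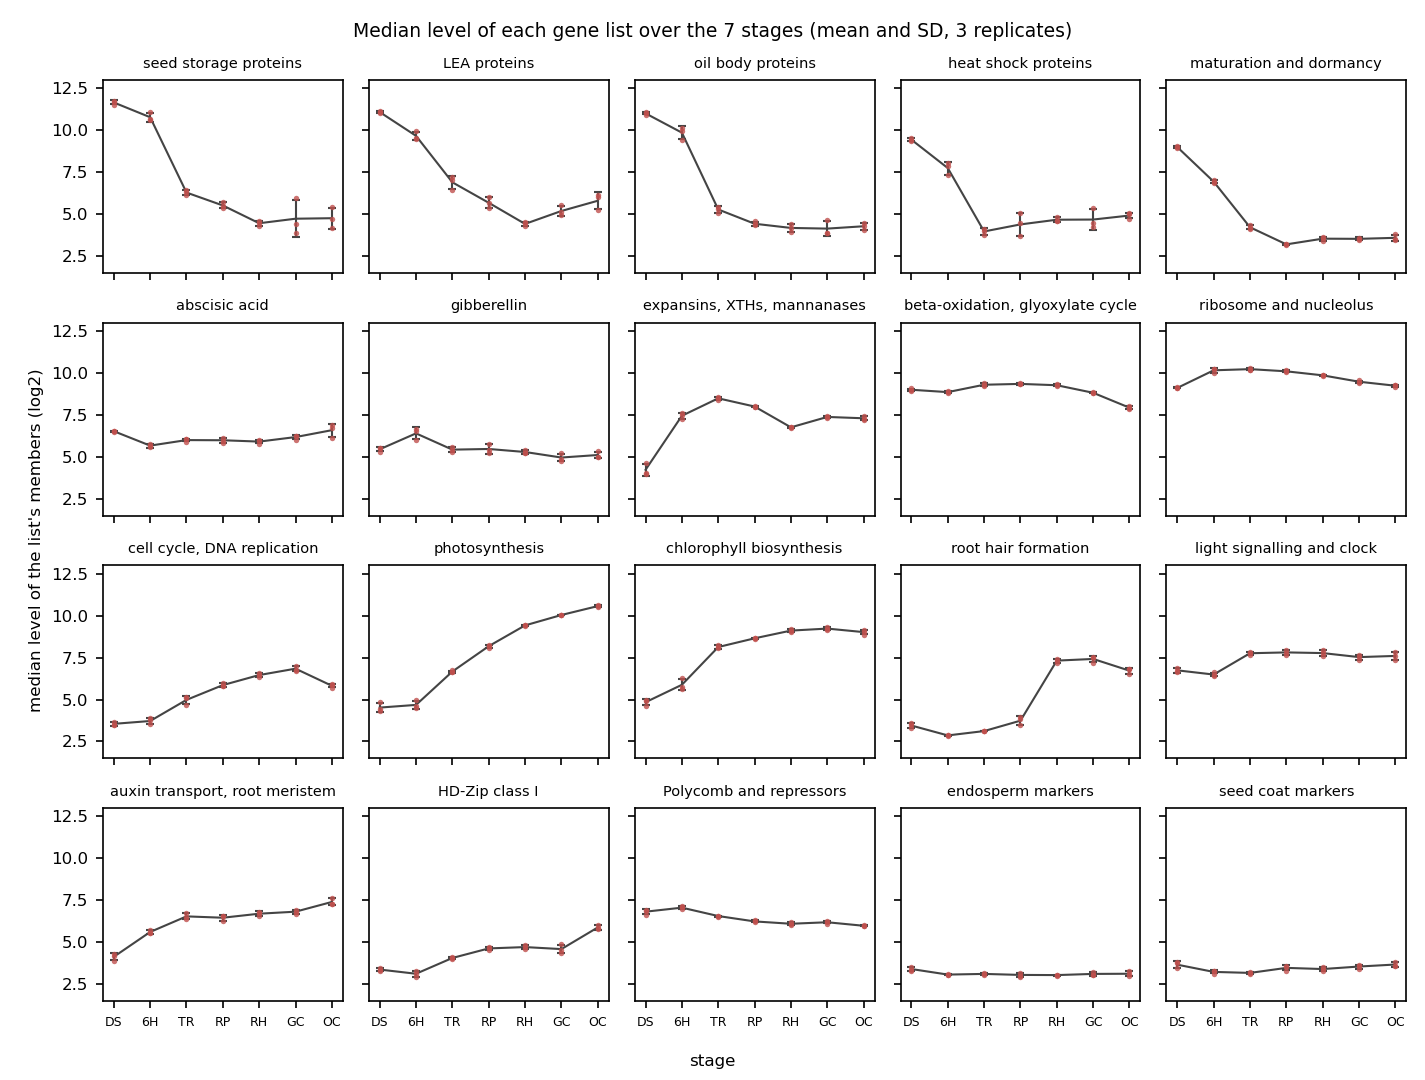
Median level (log2) of the measured members of each of the 20 gene lists at the 7 stages; points are the 3 replicates, and lines and bars give the mean and SD. The storage protein list is at 11.66 in dry seed and 4.76 at OC, and the photosynthesis list at 4.52 and 10.57.

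The lists were tested against all other genes with camera in each of the 7 comparisons, and 65 of the 140 tests passed, 30 of them upward. With a correlation between genes estimated from the data 18 passed, and each p below that is given "with an estimated correlation" comes from that test. When the 21 arrays were grouped at random, 24 of 100 groupings, the real one included, gave as many passing list tests as the real stages, so the number of passing tests does not set these stages apart from random groupings.

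The step from DS to 6H may include the cold and the light, since the start of the 6 h is not stated. GA3OX2 (AT1G80340), which encodes a gibberellin 3-oxidase that makes bioactive gibberellin, had the largest rise at 7.11 ± 0.19 (adjusted p = 4.4e-16), from a level of 3.44 to 10.55. Its paralog GA3OX1 (AT1G15550) rose by 5.48 ± 0.18, the gibberellin-responsive GASA6 (AT1G74670) by 6.67 ± 0.19, and the expansin genes EXPA10 (AT1G26770) and EXPA1 (AT1G69530) by 6.66 ± 0.18 and 5.87 ± 0.19. DOG1 (AT5G45830), a dormancy regulator, fell by 4.08 ± 0.15 (adjusted p = 3.9e-14), and HSFA9, a seed-specific heat shock factor, fell by 5.49 ± 0.2 to a level of 3.97.

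Other genes among the largest rises were AT1G28660 (6.32 ± 0.25) and the serine carboxypeptidase-like genes scpl20 (AT4G12910, 6.14 ± 0.36) and scpl44 (AT1G43780, 5.93 ± 0.43). The largest falls included AT4G11911 (-5.82 ± 0.17), SWEET6 (-5.65 ± 0.17), AT5G06755 (-5.5 ± 0.17) and AT1G60750 (-5.48 ± 0.15). All 3 arrays of one stage lay beyond all 3 of the other for these genes, as for all the largest rises and falls named in the later steps.

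Of the 28 expansins, XTHs and mannanases 20 rose, 19 of them at least 2-fold, 4 fell and 4 did not pass, with a median change of 2.84 (adjusted p = 2.5e-08, and adjusted p = 0.054 with an estimated correlation). EXPA9 (AT5G02260) rose by 5.44 ± 0.12 and EXPA2 (AT5G05290) by 5.34 ± 0.35, and in dry seed EXPA2 had an SD of 0.96, with replicate 2 the highest. All 23 genes of the ribosome and nucleolus list rose, 14 of them at least 2-fold (median 1.1, adjusted p = 1.1e-10, and adjusted p = 0.03 with an estimated correlation). Among these the fibrillarin gene FIB2 (AT4G25630) rose by 2.11 ± 0.11 and the ribosomal protein genes RPS6 (AT4G31700) and RPS5B (AT2G37270) by 1.84 ± 0.1 and 1.74 ± 0.12.

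Of the 14 auxin transport and root meristem genes 9 rose and 1 fell (median 1.07, adjusted p = 0.0022, and adjusted p = 0.11 with an estimated correlation). The auxin influx carrier gene AUX1 (AT2G38120) rose by 4.43 ± 0.12 and the efflux carrier genes PIN7 (AT1G23080) and EIR1 (AT5G57090, PIN2) by 3.78 ± 0.19 and 2.49 ± 0.15. Chlorophyll biosynthesis had 10 of 15 genes up and 2 down (median 0.92, adjusted p = 0.019, and adjusted p = 0.2 with an estimated correlation, and adjusted p = 0.068 without dim genes and 0.062 without genes near the floor). Here CRD1 (AT3G56940) rose by 2.02 ± 0.19 and CHLI1 (AT4G18480) by 1.88 ± 0.13, while CH1 (AT1G44446), the gene of chlorophyllide a oxygenase, fell by 2.5 ± 0.1. Within the gibberellin list 12 of 23 genes rose and 7 fell (median 0.69, adjusted p = 0.068). The DELLA gene RGA1 (AT2G01570) rose by 2.81 ± 0.15, and the receptor genes GID1A (AT3G05120) and GID1C (AT5G27320) changed by -2.34 ± 0.14 and -1.55 ± 0.16.

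In the LEA list, genes of late embryogenesis abundant proteins, 13 of 15 fell (median -1.29, adjusted p = 0.0023, and adjusted p = 0.42 with an estimated correlation). Among them were AT3G22490 (RAB28) at -3.79 ± 0.27 and ATECP31 (AT3G22500) at -3.48 ± 0.24. Among 14 heat shock genes 12 fell (median -1.47, adjusted p = 0.00081, and adjusted p = 0.2 with an estimated correlation), and HSP101 (AT1G74310) changed by -2.95 ± 0.28. Maturation and dormancy regulators had 7 of 10 down and 2 up (median -1.34, adjusted p = 0.039, and adjusted p = 0.14 with an estimated correlation, adjusted p = 0.091 on median-centred arrays and 0.12 on arrays centred on reference genes). ABI5 (AT2G36270) fell by 1.88 ± 0.19 and FUS3 (AT3G26790) fell by 2.49 ± 0.19, whereas ABI4 (AT2G40220) rose by 3.2 ± 0.14. Of the 10 storage protein genes 6 fell (median -0.81, adjusted p = 0.13), and the cruciferin gene CRA1 (AT5G44120) had a change of -0.37 ± 0.29 (adjusted p = 0.26). The oil body list had 5 of 6 genes down (median -1.14, adjusted p = 0.066).

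Abscisic acid genes fell in 9 of 17 cases and rose in 3 (median -0.46, adjusted p = 0.17). The zeaxanthin epoxidase gene ABA1 (AT5G67030) changed by -2.51 ± 0.12, the phosphatase genes ABI2 (AT5G57050) and HAB1 (AT1G72770) by -2.62 ± 0.26 and -2.38 ± 0.17, and the kinase gene OST1 (AT4G33950) by 1.31 ± 0.21. Of 35 cell cycle genes 16 rose and 13 fell, with a median of 0 and a mean of 0.52, and the median was 0.2 after a further quantile normalization, with 17 up and 7 down, and -0.37 on median-centred arrays (an upward test, adjusted p = 0.15). The replication genes TSO2 (AT3G27060), MCM3 (AT5G46280) and MCM2 (AT1G44900) rose by 3.11 ± 0.15, 2.9 ± 0.17 and 2.86 ± 0.16, and the mitotic genes TPX2 (AT1G03780) and AUR2 (AT2G25880) changed by -1.23 ± 0.14 and -1.14 ± 0.15. Photosynthesis genes rose in 17 of 42 cases and fell in 8 (median 0.2, -0.17 on median-centred arrays, adjusted p = 0.17). Members included RBCS2B (AT5G38420) at 2.44 ± 0.26 and LHCB4.1 (AT5G01530) at -2.26 ± 0.1.

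In the glyoxylate cycle ICL (AT3G21720) and MLS (AT5G03860), for isocitrate lyase and malate synthase, had changes of 0 ± 0.09 (adjusted p = 0.98) and -0.03 ± 0.1 (adjusted p = 0.8). Over their list 6 of 18 genes rose and 4 fell (median 0.02, -0.35 on median-centred arrays, adjusted p = 0.59). HD-Zip class I genes rose in 6 of 16 cases and fell in 7, with a median of -0.28, a mean of 0.35 and an upward test (adjusted p = 0.58), and after a further quantile normalization the median was 0.12, with 7 up and 2 down. The study took up HB13 from these samples, so the HD-Zip counts here and below are not independent evidence of a direction. ATHB13 (AT1G69780, HB13) fell by 0.35 ± 0.15 (adjusted p = 0.04), but its change was 0.05 after a further quantile normalization. It did not pass without DS replicate 2, DS replicate 3, 6H replicate 1 or 6H replicate 3, with changes from -0.2 to -0.39, or with a trended and robust prior (-0.35) or array weights (-0.21). HB-3 (AT5G15150) rose by 3.7 ± 0.15. Polycomb and repressor genes rose in 7 of 12 cases and fell in 2 (median 0.28, -0.09 on median-centred arrays, adjusted p = 0.12). Examples were CLF (AT2G23380) at 2.21 ± 0.16 and RING1A (AT5G44280) at -2.16 ± 0.16. Light signalling had 5 of 21 up and 8 down (median -0.25, adjusted p = 0.63). Members included SPT (AT4G36930) at 3.11 ± 0.17 and ELIP1 (AT3G22840) at -3.18 ± 0.18. Root hair genes rose in 2 of 24 cases and fell in 13 (median -0.48, adjusted p = 0.088), and 5 fell after a further quantile normalization (median -0.15). Endosperm markers had 6 of 8 down and 1 up (median -0.44, adjusted p = 0.33), against 0 down after that normalization (median -0.09). Seed coat markers had 7 of 12 down and 3 up (median -0.47, adjusted p = 0.61), against 4 down (median -0.16). Their median levels were low, from 3.4 to 3.66 in dry seed and from 2.86 to 3.23 at 6 h. Of the 4550 genes under the floor at every stage 2456 fell in this step, with a median of -0.4, against 404 and -0.05 after a further quantile normalization.

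By limma 4070 genes rose and 2965 fell at least 2-fold, 25.3% of all genes, and 8220 and 11120 did so at the adjusted p alone. The median of all genes was -0.23, and it was -0.04 after a further quantile normalization, -0.6 on median-centred arrays and -0.61 on arrays centred on reference genes. On median-centred arrays 2457 genes rose and 6159 fell, and on arrays centred on reference genes 2429 rose and 6303 fell, so the split between rises and falls depended on the scaling. In dry seed replicate 2, 34 of 36 genes that were abundant from TR to OC and low in replicates 1 and 3 lay above both other replicates, by a median of 1.47, against 2 of 30 for replicate 1 and 0 of 25 for replicate 3 with the same choice of genes. Adjusted over the list alone, the counts were the same except for expansins and XTHs (20 rose and 5 fell), cell cycle (16 rose and 14 fell), photosynthesis (16 rose and 8 fell), light signalling (5 rose and 7 fell), HD-Zip (6 rose and 8 fell) and seed coat (4 rose and 7 fell).

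The step from 6 h of imbibition to testa rupture covers embryo swelling. Most genes of the photosynthesis list rose and all storage protein genes fell. ELIP1 and ELIP2 (AT4G14690), for early light-induced proteins of the thylakoid, rose by 6.9 ± 0.18 (adjusted p = 2.2e-15) and 6.16 ± 0.18, and ELIP1 reached a level of 10.44. SESA4 (AT4G27170), a 2S albumin gene, fell by 6.2 ± 0.33, the cruciferin gene CRU2 (AT1G03880) fell by 5.27 ± 0.35, and CRA1 fell by 4.68 ± 0.29. The abscisic acid 8'-hydroxylase genes CYP707A1 (AT4G19230) and CYP707A3 (AT5G45340), whose products break the hormone down, rose by 4.13 ± 0.18 and 3.31 ± 0.17, and their paralog CYP707A2 (AT2G29090) fell by 1.51 ± 0.25.

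The largest rises further held the beta-xylosidase gene BXL1 (AT5G49360, 6.02 ± 0.25), BGLU21 (AT1G66270, 5.81 ± 0.24), AT5G26260 (5.7 ± 0.43) and CER1 (AT1G02205, 5.49 ± 0.19), a gene of wax alkane synthesis. The largest falls further held MLP31 (AT1G70840) (-6.34 ± 0.24), from a level of 9.57 to 3.24, AT2G29500 (HSP17.6B, -5.88 ± 0.37), the seed aquaporin gene TIP3;1 (AT1G73190) (-5.86 ± 0.27) and AtMT4b (AT2G23240) (-5.64 ± 0.28).

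All 10 storage protein genes fell, with a median of -3.94 (adjusted p = 2.5e-08, and adjusted p = 0.091 with an estimated correlation), and so did all 6 oil body genes (median -4.85, adjusted p = 7.4e-07, and adjusted p = 0.058 with an estimated correlation). Among them were the oleosin genes OLEO2 (AT5G40420) and OLEO1 (AT4G25140) at -5.12 ± 0.24 and -4.88 ± 0.32. Of 15 LEA genes 14 fell (median -2.95, adjusted p = 1.1e-08, and adjusted p = 0.14 with an estimated correlation). Examples were M10 (AT2G41280) at -4.72 ± 0.23, RAB18 (AT5G66400) at -3.81 ± 0.32 and EM1 (AT3G51810) at -3.67 ± 0.25. Heat shock genes fell in 13 of 14 cases (median -3.01, adjusted p = 1.5e-08, and adjusted p = 0.054 with an estimated correlation). Maturation and dormancy regulators fell in 8 of 10 cases (median -1.24, adjusted p = 0.00021, and adjusted p = 0.023 with an estimated correlation). Among them were AHG1 (AT5G51760), a phosphatase gene of abscisic acid signalling, at -4.27 ± 0.16, FUS3 at -2.12 ± 0.19, DOG1 at -1.59 ± 0.15 and ABI5 at -1.32 ± 0.19.

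Photosynthesis genes rose in 34 of 42 cases, 30 of them at least 2-fold (median 1.53, adjusted p = 4.9e-15, and adjusted p = 0.067 with an estimated correlation). RBCS1B (AT5G38430), a Rubisco small subunit gene, rose by 4.55 ± 0.27, LHCB5 (AT4G10340) by 3.05 ± 0.2 and PSBQA (AT4G21280) by 2.82 ± 0.18, and LHCB3 (AT5G54270) had 0.33 ± 0.16 (adjusted p = 0.11). Chlorophyll biosynthesis genes rose in 14 of 15 cases (median 1.61, adjusted p = 4.3e-10, and adjusted p = 0.0068 with an estimated correlation). Members included the protochlorophyllide oxidoreductase gene PORB (AT4G27440) at 4.28 ± 0.22, the Mg-chelatase gene GUN5 (AT5G13630, CHLH) at 3.97 ± 0.19 and HEMA1 (AT1G58290) at 2.55 ± 0.18. PORA (AT5G54190) had 0.21 ± 0.13 (adjusted p = 0.18). Cell cycle and replication genes rose in 30 of 35 cases, 24 at least 2-fold (median 1.37, adjusted p = 5.7e-11, and adjusted p = 0.043 with an estimated correlation). CYCA2;3 (AT1G15570) rose by 2.23 ± 0.24, SYP111 (AT1G08560, KNOLLE, a syntaxin of cytokinesis) by 1.88 ± 0.21 and PRL (AT4G02060, MCM7) by 1.96 ± 0.18, and CYCB1;1 (AT4G37490) had -0.2 ± 0.19 (adjusted p = 0.43).

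Expansins, XTHs and mannanases rose in 17 of 28 cases and fell in 5 (median 0.65, adjusted p = 0.0051, and adjusted p = 0.27 with an estimated correlation). Examples were XTH18 (AT4G30280) at 4.18 ± 0.16 and EXPA10 at -1.28 ± 0.18. Gibberellin genes fell in 14 of 23 cases and rose in 3 (median -0.58, adjusted p = 0.012, and adjusted p = 0.061 with an estimated correlation). GA20OX3 (AT5G07200) and GA3OX1 changed by -3.51 ± 0.18 and -1.98 ± 0.18, and the receptor gene GID1B (AT3G63010) rose by 2.34 ± 0.16. Auxin genes rose in 9 of 14 cases and fell in 1 (median 0.6, adjusted p = 0.012, and adjusted p = 0.18 with an estimated correlation). Members included PIN4 (AT2G01420) at 1.93 ± 0.19 and PIN3 (AT1G70940) at 1.88 ± 0.16. Light signalling had 10 of 21 up and 7 down (median 0.16, adjusted p = 0.088). LHY (AT1G01060), a clock gene, rose by 3.86 ± 0.2 and HY5 (AT5G11260) by 1.51 ± 0.14, and PIF4 (AT2G43010) changed by -2.29 ± 0.18. HD-Zip genes rose in 7 of 16 cases and fell in 2 (median 0.28, adjusted p = 0.079). ATHB13 had 1.57 ± 0.15 (adjusted p = 3e-08).

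Abscisic acid genes fell in 9 of 17 cases and rose in 4 (median -0.52, adjusted p = 0.3), and beta-oxidation genes rose in 8 of 18 and fell in 2 (median 0.09, adjusted p = 0.071). ICL had 0.07 ± 0.09 (adjusted p = 0.58). Ribosome genes rose in 2 of 23 cases and fell in 4, with a median of 0.07, a mean of -0.03 and a downward test (adjusted p = 0.9). Polycomb genes fell in 5 of 12 cases and rose in 1 (median -0.22, adjusted p = 0.089), and root hair genes rose in 8 of 24 and fell in 1 (median 0.23, adjusted p = 0.088). Endosperm markers fell in 3 of 8 cases, with a median of 0.06 and a mean of -0.35, and the median was -0.07 after a further quantile normalization (a downward test, adjusted p = 0.5). EPR1 (AT2G27380), an extensin-like gene of the germinating endosperm, fell by 1.53 ± 0.19. Seed coat markers rose in 4 of 12 cases (median 0.03, -0.12 after a further quantile normalization, adjusted p = 0.096). An example was MUM2 (AT5G63800) at 2.98 ± 0.13.

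By limma 2723 genes rose and 2041 fell at least 2-fold, 17.1% of all genes. At the adjusted p alone 6179 rose and 7268 fell. On arrays centred on reference genes 3212 rose and 1562 fell, and the median of all genes was 0.14 in place of 0.01. The counts adjusted over the list alone were the same except for heat shock proteins (0 rose and 14 fell), expansins and XTHs (18 rose and 5 fell), ribosome (0 rose and 4 fell) and Polycomb (1 rose and 6 fell).

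The step from testa rupture to radicle protrusion covers the completion of germination, with the radicle leaving the endosperm. It had the fewest genes with a 2-fold change of the 7 comparisons, 863, although limma's treat, a test against a 2-fold change, gave 181 here and 157 from RH to GC. The largest rises were those of AT1G23720 at 4.85 ± 0.18 (adjusted p = 5.5e-13), AT3G54580 at 4.8 ± 0.16 and AT3G28550 at 4.68 ± 0.17. PORA, a protochlorophyllide oxidoreductase gene, rose by 2.03 ± 0.13, from a level of 2.97 to 5, and LHCB3, a light-harvesting gene, by 1.93 ± 0.16. The LEA gene AtLEA4-1 (AT1G32560) fell by 3.17 ± 0.27 (adjusted p = 6.9e-08) and ABI5 fell by 1.73 ± 0.19.

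Photosynthesis genes rose in 36 of 42 cases, 28 of them at least 2-fold (median 1.4, adjusted p = 5.4e-45, and adjusted p = 0.0068 with an estimated correlation). PSAK (AT1G30380) rose by 2.48 ± 0.18, LHCB5 by 2.44 ± 0.2 and the plastocyanin gene PETE1 (AT1G76100) by 2.32 ± 0.15. RBCS1A (AT1G67090) rose by 0.32 ± 0.1 (adjusted p = 0.04), which did not pass without any single array of TR or RP, or without 6H replicate 2 or RH replicate 2, with changes from 0.27 to 0.34. It did not pass either after a further quantile normalization (0.3), on arrays centred on the median (0.31) or on reference genes (0.31), or with a replicate term (0.32). Chlorophyll biosynthesis genes rose in 11 of 15 cases (median 0.65, adjusted p = 6.6e-10, and adjusted p = 0.0068 with an estimated correlation). GUN5 had 1.28 ± 0.19. Cell cycle genes rose in 17 of 35 cases (median 0.44, adjusted p = 1.6e-09, and adjusted p = 0.058 with an estimated correlation). Among them were the kinase gene AUR1 (AT4G32830) at 1.7 ± 0.19, the kinesin gene HIK (AT1G18370) at 1.51 ± 0.2 and CYCB1;4 (AT2G26760) at 1.47 ± 0.16. Root hair genes rose in 10 of 24 cases and fell in 1 (median 0.4, adjusted p = 1.6e-07, and adjusted p = 0.099 with an estimated correlation). RHD2 (AT5G51060), which encodes an NADPH oxidase of root hair growth, rose by 1.98 ± 0.19, RHS19 (AT5G67400) by 2.06 ± 0.17, the bHLH factor gene RSL4 (AT1G27740) by 1.22 ± 0.2 and the expansin gene EXPA7 (AT1G12560) by 0.94 ± 0.18.

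LEA genes fell in 8 of 15 cases (median -1.08, adjusted p = 1.3e-07, and adjusted p = 0.18 with an estimated correlation). Among them were LEA4-5 (AT5G06760) at -2.32 ± 0.33, ECP63 (AT2G36640) at -1.77 ± 0.29 and EM1 at -1.41 ± 0.25. Storage protein genes fell in 3 of 10 cases (median -0.74, adjusted p = 0.0021, and adjusted p = 0.32 with an estimated correlation), and CRA1 had -0.74 ± 0.29 (adjusted p = 0.099). Oil body genes fell in 3 of 6 cases (median -0.76, adjusted p = 0.0018, and adjusted p = 0.2 with an estimated correlation). Among them was the caleosin gene ATS1 (AT4G26740) at -1.1 ± 0.25. Maturation and dormancy regulators fell in 5 of 10 cases (median -0.49, adjusted p = 1.4e-05, and adjusted p = 0.012 with an estimated correlation). Examples were AHG1 at -1.92 ± 0.16 and SOM (AT1G03790) at -1.71 ± 0.22. Gibberellin genes fell in 8 of 23 cases and rose in 1 (median -0.29, adjusted p = 0.00082, and adjusted p = 0.021 with an estimated correlation). Members included GA20OX3 at -1.19 ± 0.18 and the DELLA genes RGL3 (AT5G17490) and GAI (AT1G14920) at -0.87 ± 0.13 and -0.71 ± 0.12. Ribosome genes fell in 5 of 23 cases (median -0.12, adjusted p = 0.0041, and adjusted p = 0.27 with an estimated correlation). Among them was NOP56 (AT1G56110) at -0.68 ± 0.1.

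Light signalling genes rose in 5 of 21 cases and fell in 1 (median 0.09, adjusted p = 0.023, and adjusted p = 0.26 with an estimated correlation), and the test did not pass without TR replicate 1 (adjusted p = 0.073) or RP replicate 1 (adjusted p = 0.097), or with camera on ranks (adjusted p = 0.07). HD-Zip genes rose in 5 of 16 cases (median 0.07, adjusted p = 0.016, and adjusted p = 0.081 with an estimated correlation), and the test did not pass with camera on ranks (adjusted p = 0.1). Examples were ATHB13 at 1.27 ± 0.15 and HB20 (AT3G01220) at 1.75 ± 0.2. Polycomb genes fell in 2 of 12 cases (median -0.23, adjusted p = 0.0057, and adjusted p = 0.081 with an estimated correlation). Expansins and XTHs rose in 4 of 28 cases and fell in 6 (median -0.13, adjusted p = 0.39). Members included EXPA17 (AT4G01630) at 3.09 ± 0.21 and EXPA15 (AT2G03090) at -1.32 ± 0.18. Abscisic acid genes rose in 2 of 17 cases and fell in 4 (median -0.07, adjusted p = 0.53). Auxin genes rose in 2 of 14 cases and fell in 2 (median 0.03, adjusted p = 0.67). Beta-oxidation genes rose in 2 of 18 cases and fell in 1, with a median of -0.02, a mean of 0.06 and an upward test (adjusted p = 0.61), and ICL and MLS had 0.13 ± 0.09 (adjusted p = 0.4) and 0.12 ± 0.1 (adjusted p = 0.55).

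Of the heat shock genes 1 of 14 rose (median 0.07, adjusted p = 0.16), and of the seed coat markers 1 of 12 (median 0.02, -0.05 after a further quantile normalization, adjusted p = 0.51). By limma 0 of 8 endosperm markers rose and 0 fell, as when adjusted over the list alone, against 0 up and 1 down at an unadjusted p under 0.05 (median -0.04, adjusted p = 0.61). Over all genes 650 rose and 213 fell at least 2-fold, 3.11%, and 2177 and 2069 did so at the adjusted p alone. With adjustment over the list alone other counts were the same except for storage proteins (0 rose and 6 fell), LEA proteins (0 rose and 12 fell), abscisic acid (3 rose and 4 fell), gibberellin (2 rose and 10 fell), expansins and XTHs (5 rose and 9 fell), ribosome (0 rose and 7 fell), cell cycle (17 rose and 1 fell), photosynthesis (38 rose and 0 fell), chlorophyll biosynthesis (13 rose and 0 fell) and Polycomb (0 rose and 3 fell).

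In the step from radicle protrusion to root hair formation most genes of the root hair list rose. EXPA7, a root hair expansin gene, rose by 4.2 ± 0.18 (adjusted p = 1.3e-12), from a level of 3.98 to 8.18. RHS13 (AT4G02270) rose by 6.04 ± 0.16, the proline-rich protein gene PRP1 (AT1G54970) by 5.82 ± 0.17 and the xyloglucan endotransglucosylase gene XTH14 (AT4G25820) by 5.74 ± 0.19. The largest rise was that of AT5G57625 at 6.72 ± 0.15 (adjusted p = 5.1e-17), and the extensin genes EXT12 (AT4G13390) and EXT6 (AT2G24980) rose by 6.09 ± 0.11 and 6.06 ± 0.26 and XTH13 (AT5G57540) by 6.08 ± 0.23. The seed maturation regulator gene ABI3 (AT3G24650) fell by 3.25 ± 0.13 (adjusted p = 5.5e-13), and EXPA2 fell by 3.16 ± 0.35.

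Root hair genes rose in 20 of 24 cases, all of them at least 2-fold, with a median of 3.21 (adjusted p = 4.4e-35, and adjusted p = 0.0035 with an estimated correlation). RSL4 rose by 2.45 ± 0.2, and among members that did not pass RSL2 (AT4G33880) had 0.6 ± 0.23 (adjusted p = 0.066) and LRX2 (AT1G62440) had 0.21 ± 0.25 (adjusted p = 0.65). All 15 chlorophyll biosynthesis genes rose (median 0.74, adjusted p = 7.1e-10, and adjusted p = 0.0068 with an estimated correlation), PORA by 3.41 ± 0.13 and GUN4 (AT3G59400) by 0.96 ± 0.16. Photosynthesis genes rose in 35 of 42 cases, 20 of them at least 2-fold (median 0.98, adjusted p = 1.7e-29, and adjusted p = 0.018 with an estimated correlation). LHCB2.2 (AT2G05070) rose by 3.65 ± 0.22, PETE1 by 2.32 ± 0.15, PSAK by 2.16 ± 0.18 and LHCB3 by 1.92 ± 0.16.

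The gibberellin-responsive GASA6 fell by 3.49 ± 0.19, and AT1G29080, the largest fall, fell by 4.47 ± 0.23. LEA genes fell in 9 of 15 cases and rose in 1 (median -0.92, adjusted p = 0.00018, and adjusted p = 0.31 with an estimated correlation). Examples were LEA18 (AT2G35300) at -3.12 ± 0.4 and LEA7 (AT1G52690) at -2.3 ± 0.34. Storage protein genes fell in 3 of 10 cases (median -0.76, adjusted p = 0.0067, and adjusted p = 0.39 with an estimated correlation) and oil body genes in 3 of 6 (median -0.63, adjusted p = 0.059). Expansins, XTHs and mannanases fell in 12 of 28 cases and rose in 2 (median -0.41, adjusted p = 0.0063, and adjusted p = 0.29 with an estimated correlation). The test of this list did not pass with camera on ranks (adjusted p = 0.079). Members included XTH15 (AT4G14130) at -3.12 ± 0.22 and EXPA8 (AT2G40610) at -2.44 ± 0.17. Maturation regulators fell in 3 of 10 cases and rose in 1 (median -0.18, adjusted p = 0.045, and adjusted p = 0.16 with an estimated correlation), ABI4 at -2.02 ± 0.14 and FUS3 by 1.14 ± 0.19. The call of this list was lost without DS replicate 2 (adjusted p = 0.054), RP replicate 3 (0.059), OC replicate 2 (0.051) or both of the replicates 2 (0.062). It was also lost with a replicate term (0.054), on median-centred arrays (0.051), with array weights (0.069), without dim genes (0.056), without genes near the floor (0.055) and with camera on ranks (0.16).

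Ribosome genes fell in 8 of 23 cases (median -0.22, adjusted p = 4.4e-05, and adjusted p = 0.14 with an estimated correlation), NOP56 at -0.79 ± 0.1, and Polycomb genes in 5 of 12 (median -0.3, adjusted p = 0.01, and adjusted p = 0.1 with an estimated correlation). Cell cycle genes rose in 14 of 35 cases and fell in 8 (median 0.43, adjusted p = 0.098). The mitotic genes CYCA1;1 (AT1G44110) and TPX2 rose by 1.35 ± 0.17 and 1.05 ± 0.14, and the replication genes MCM6 (AT5G44635) and MCM2 changed by -0.72 ± 0.17 and -0.67 ± 0.16. Gibberellin genes rose in 5 of 23 cases and fell in 6 (median -0.02, 0.04 on arrays centred on reference genes, adjusted p = 0.66). An example was the DELLA gene RGL2 (AT3G03450) at -1.88 ± 0.15. Auxin genes rose in 3 of 14 cases and fell in 2 (median 0.05, 0 after a further quantile normalization, adjusted p = 0.51). An example was the influx carrier gene LAX3 (AT1G77690) at 1.67 ± 0.2. HD-Zip genes rose in 3 of 16 cases and fell in 3, with a median of 0.12, a mean of -0.02 and an upward test (adjusted p = 0.93), against a downward direction by fry, and ATHB13 rose by 0.53 ± 0.15, or 0.48 without RH replicate 1, where it did not pass.

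Abscisic acid genes rose in 3 of 17 cases and fell in 2 (median 0.13, adjusted p = 0.58). Light signalling genes rose in 3 of 21 and fell in 2 (median 0.1, adjusted p = 0.36). An example was the chalcone synthase gene TT4 (AT5G13930) at 1.41 ± 0.14. Beta-oxidation genes rose in 2 of 18 cases and fell in 1 (median -0.13, adjusted p = 0.22). ICL had -0.05 ± 0.09 (adjusted p = 0.77). Heat shock genes rose in 1 of 14 cases and fell in 1 (median -0.12, adjusted p = 0.68). Endosperm markers fell in 1 of 8 cases, with a median of 0.03, a mean of -0.06 and a median of -0.03 after a further quantile normalization (a downward test, adjusted p = 0.94), and seed coat markers in 1 of 12 (median -0.1, adjusted p = 0.41). Over all genes 1014 rose and 483 fell at least 2-fold by limma, 5.39%, and 3185 and 3304 did so at the adjusted p alone. List counts adjusted over the list alone differed for storage proteins (0 rose and 5 fell), oil body proteins (0 rose and 4 fell), gibberellin (5 rose and 7 fell), expansins and XTHs (3 rose and 13 fell), beta-oxidation (2 rose and 7 fell), ribosome (0 rose and 9 fell), cell cycle (16 rose and 10 fell), photosynthesis (39 rose and 0 fell), root hair formation (21 rose and 0 fell), auxin (5 rose and 3 fell) and Polycomb (0 rose and 6 fell).

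The step from root hair formation to greening cotyledons continued the rise of photosynthetic transcripts. CA1 (AT3G01500), a carbonic anhydrase gene of the chloroplast, had the largest rise at 5.54 ± 0.17 (adjusted p = 6.8e-14), from a level of 3.68 to 9.22. The light-harvesting genes LHB1B1 (AT2G34430, LHCB1.4), LHCB2.2 and LHCB3 rose by 4.62 ± 0.31, 1.34 ± 0.22 and 1.09 ± 0.16. In the cell cycle list CYCB2;4 (AT1G76310) rose by 1.38 ± 0.17 and HIK by 1.35 ± 0.2, while RNR2A (AT3G23580) and PCNA1 (AT1G07370) changed by -1.23 ± 0.19 and -0.96 ± 0.21. GA3OX2 fell by 2.22 ± 0.19 (adjusted p = 1.1e-07).

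Photosynthesis genes rose in 26 of 42 cases (median 0.54, adjusted p = 1.2e-14, and adjusted p = 0.069 with an estimated correlation), and RBCS1A had 0.05 ± 0.1 (adjusted p = 0.81). Cell cycle genes rose in 17 of 35 cases, 11 of them at least 2-fold, and fell in 6 (median 0.5, adjusted p = 0.00065, and adjusted p = 0.24 with an estimated correlation). TPX2 had 1.36 ± 0.14. Chlorophyll biosynthesis genes rose in 3 of 15 cases (median 0.22, adjusted p = 0.022, and adjusted p = 0.21 with an estimated correlation, and adjusted p = 0.051 without GC replicate 1), CH1 by 0.9 ± 0.1, and PORA had 0.34 ± 0.13 (adjusted p = 0.059). Beta-oxidation and glyoxylate cycle genes fell in 13 of 18 cases (median -0.42, adjusted p = 1.5e-08, and adjusted p = 0.0068 with an estimated correlation). Among them PMDH1 (AT2G22780) fell by 0.66 ± 0.09 and PKT3 (AT2G33150), for 3-ketoacyl-CoA thiolase, fell by 0.55 ± 0.1. Ribosome genes fell in 13 of 23 cases (median -0.3, adjusted p = 4.2e-08, and adjusted p = 0.058 with an estimated correlation). An example was NUC-L1 (AT1G48920), the nucleolin gene, at -0.57 ± 0.09.

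The largest rises further held AT1G04800 (3.97 ± 0.15) and the amino acid permease gene AAP2 (AT5G09220, 3.23 ± 0.15), and the largest falls scpl44 (-3.45 ± 0.43), AT2G05910 (-2.73 ± 0.22) and the sugar transporter gene SAG29 (AT5G13170) (-2.37 ± 0.14). Expansins, XTHs and mannanases rose in 6 of 28 cases and fell in 5 (median 0.2, adjusted p = 0.41). Examples were EXPA5 (AT3G29030) at 1.35 ± 0.19 and EXPA2 at -1.85 ± 0.35. LEA genes rose in 3 of 15 cases and fell in 1 (median 0.42, adjusted p = 0.053), LEA4-5 by 1.55 ± 0.33 and EM1 by 1.1 ± 0.25. Storage protein genes rose in 1 of 10 cases (median 0.1, adjusted p = 0.5), SESA4 by 1.06 ± 0.33 with an SD of 0.98 at GC, or 0.51 without GC replicate 2, and it did not pass there or without any single array of RH. Light signalling genes rose in 4 of 21 cases and fell in 6 (median -0.01, 0.08 on arrays centred on reference genes, adjusted p = 0.73). Members included GPRI1 (AT2G20570, GLK1), a factor of chloroplast development, at 1.05 ± 0.17 and HY5 at -0.6 ± 0.14.

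Root hair genes rose in 3 of 24 cases (median 0.2, adjusted p = 0.052), and EXPA7 and RSL4 had 0.11 ± 0.18 (adjusted p = 0.76) and -0.22 ± 0.2 (adjusted p = 0.54). Abscisic acid genes rose in 2 of 17 cases and fell in 3 (median -0.09, 0 on arrays centred on reference genes, adjusted p = 0.61). Gibberellin genes rose in 1 and fell in 2 of 23 cases (median -0.02, 0.06 on arrays centred on reference genes, adjusted p = 0.86). Auxin genes rose in 2 of 14 cases (median 0.11, adjusted p = 0.25), and heat shock genes rose in 2 of 14 and fell in 1 (median 0.3, adjusted p = 0.35). Oil body genes rose in 1 of 6 cases (median 0.26, adjusted p = 0.59). Maturation regulators fell in 1 of 10 cases, ABI4 at -1.78 ± 0.14, with a list median of 0.06, a mean of -0.16 and a median of 0 after a further quantile normalization (a downward test, adjusted p = 0.43).

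By limma 0 of 16 HD-Zip genes rose and 0 fell, as when adjusted over the list alone, against 1 up and 1 down at an unadjusted p under 0.05 (median -0.07, 0.01 on arrays centred on reference genes, adjusted p = 0.83). ATHB13 had 0.2 ± 0.15 (adjusted p = 0.4). Polycomb genes fell in 1 of 12 cases (median -0.09, 0 on arrays centred on reference genes, adjusted p = 0.43), MSI1 (AT5G58230) at -0.45 ± 0.1. Endosperm markers fell in 1 of 8 cases, EPR1 at -1.3 ± 0.19, with a list median of 0.02, a mean of -0.13 and a median of -0.05 after a further quantile normalization (a downward test, adjusted p = 0.66). Seed coat markers rose in 1 of 12 cases and fell in 2, with a median of 0.12, a mean of -0.03 and an upward test (adjusted p = 0.83).

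Over all genes 723 rose and 270 fell at least 2-fold by limma, 3.57%, and 2818 and 3041 did so at the adjusted p alone. The median of all genes was 0.02, and 0.11 on arrays centred on reference genes. Adjustment over the list alone changed the counts of LEA proteins (4 rose and 1 fell), heat shock proteins (3 rose and 2 fell), abscisic acid (2 rose and 4 fell), expansins and XTHs (9 rose and 6 fell), beta-oxidation (0 rose and 16 fell), ribosome (0 rose and 18 fell), cell cycle (21 rose and 10 fell), photosynthesis (34 rose and 0 fell), chlorophyll biosynthesis (4 rose and 0 fell) and auxin (1 rose and 0 fell).

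The step from greening to opened cotyledons held the last changes before the seedling stage was complete. AT1G55990, AT3G53980 and PELPK2 had the largest rises, at 7.19 ± 0.25 (adjusted p = 4.2e-14), 6.61 ± 0.13 and 6.59 ± 0.2. Their levels at GC were 2.89, 2.58 and 2.74, all near the floor, so these changes are lower bounds. Cell cycle genes went down together, the kinesin gene HIK at -1.87 ± 0.2 and CYCB2;4 at -2.14 ± 0.17. Genes of fat mobilisation went down as well: MLS fell by 1.74 ± 0.1 (adjusted p = 1.1e-10), ICL fell by 0.72 ± 0.09, and PKT3 fell by 1.66 ± 0.1. PORA fell by 2.62 ± 0.13 (adjusted p = 4.2e-12), from a level of 8.76 to 6.14, while LHCB3 rose by 0.65 ± 0.16.

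Of 35 cell cycle genes 33 fell, 13 of them at least 2-fold (median -0.88, adjusted p = 2.3e-15, and adjusted p = 0.019 with an estimated correlation). Among them were SYP111 at -1.91 ± 0.21 and CYCB1;1 at -0.89 ± 0.19. Of 18 beta-oxidation and glyoxylate cycle genes 17 fell and 1 rose (median -0.84, adjusted p = 2.4e-12, and adjusted p = 0.0035 with an estimated correlation). An example was MFP2 (AT3G06860) at -1.65 ± 0.09. Ribosome genes fell in 15 of 23 cases (median -0.31, adjusted p = 0.00024, and adjusted p = 0.18 with an estimated correlation). Chlorophyll biosynthesis genes fell in 10 of 15 cases and rose in 2 (median -0.68, adjusted p = 0.0044, and adjusted p = 0.14 with an estimated correlation). Examples were GSA1 (AT5G63570) at -1.31 ± 0.09 and HEMA1 at 0.71 ± 0.18. Root hair genes fell in 18 of 24 cases and rose in 1 (median -0.66, adjusted p = 0.00021, and adjusted p = 0.22 with an estimated correlation). Among them were EXPA18 (AT1G62980) at -1.28 ± 0.2 and EXPA7 at -0.99 ± 0.18, and RSL2 rose by 1.38 ± 0.23.

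Photosynthesis genes rose in 21 of 42 cases (median 0.43, adjusted p = 7.8e-07, and adjusted p = 0.22 with an estimated correlation), LHB1B1 by 1.39 ± 0.31 and LHCB2.1 (AT2G05100) by 1.35 ± 0.3, and RBCS1A had 0.19 ± 0.1 (adjusted p = 0.16). LEA genes rose in 8 of 15 cases (median 0.89, adjusted p = 0.0013, and adjusted p = 0.39 with an estimated correlation). LEA7 rose by 3.17 ± 0.34 (adjusted p = 4.7e-07), LEA4-5 by 2.24 ± 0.33 and RAB18 by 1.73 ± 0.32. The SD of LEA7 among the OC replicates was 1.18, and replicate 2 lay below replicates 1 and 3 in all 22 genes of a water-deficit list chosen after the data were seen, with a median difference of -0.86. HD-Zip genes rose in 5 of 16 cases (median 0.11, adjusted p = 0.1). HB-7 (AT2G46680) and HB-12 (AT3G61890), which respond to water deficit, rose by 2.91 ± 0.31 and 2.12 ± 0.35, HB-7 with an SD of 0.96 at OC, and ATHB13 had 0.34 ± 0.15 (adjusted p = 0.084).

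Maturation regulators rose in 4 of 10 cases and fell in 2 (median 0.26, adjusted p = 0.2). Members included SOM at 2.11 ± 0.22, ABI3 at 1.76 ± 0.13 and DOG1 at 0.51 ± 0.15, or 0.42 without OC replicate 2, 0.41 without GC replicate 3, 0.34 after a further quantile normalization and 0.44 on median-centred arrays, where DOG1 did not pass. Abscisic acid genes rose in 7 of 17 cases and fell in 3 (median 0.13, adjusted p = 0.23). Examples were ABA1 at 1.11 ± 0.12 and CYP707A1 at -1.01 ± 0.18. Light signalling genes rose in 7 of 21 cases and fell in 5 (median 0.06, -0.01 on median-centred arrays, adjusted p = 0.67). Members included PIF4 at 1.74 ± 0.18 and SPT at -1.08 ± 0.17. Expansins, XTHs and mannanases rose in 9 of 28 cases and fell in 5, with a median of -0.03, a mean of 0.13 and an upward test (adjusted p = 0.55), and the median was 0.19 on arrays centred on reference genes. EXPA8 had 1.79 ± 0.17 and EXP3 (AT2G37640, EXPA3) had -1.31 ± 0.14. Gibberellin genes rose in 3 of 23 cases and fell in 7, with a median of 0 and a mean of -0.1, and a median of 0.21 on arrays centred on reference genes (a downward test, adjusted p = 0.64). GA3OX2 fell by 1.22 ± 0.19.

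Auxin genes rose in 5 of 14 cases (median 0.24, adjusted p = 0.07) and seed coat markers in 5 of 12 (median 0.2, adjusted p = 0.15), TT8 (AT4G09820) by 1.44 ± 0.2. Heat shock genes rose in 3 of 14 cases and fell in 1 (median 0.45, adjusted p = 0.096). Storage protein genes fell in 1 of 10 cases with a median of 0.12 and an upward test (adjusted p = 0.86), and oil body genes in 1 of 6 (median -0.01, 0.2 on arrays centred on reference genes, adjusted p = 0.93). Polycomb genes fell in 5 of 12 cases (median -0.22, 0 on arrays centred on reference genes, adjusted p = 0.1), CLF at -0.7 ± 0.16. By limma 0 of 8 endosperm markers rose and 0 fell, and at an unadjusted p under 0.05 it was 0 up and 1 down (median 0.01, mean -0.04, and a median of -0.02 after a further quantile normalization, a downward test, adjusted p = 0.92).

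By limma 1504 genes rose and 840 fell at least 2-fold, 8.43% of all genes, and 4471 and 4988 did so at the adjusted p alone. On arrays centred on reference genes 2226 rose and 499 fell, and the median of all genes was 0.18 in place of -0.03. Counts adjusted over the list alone were the same except for storage proteins (0 rose and 0 fell), ribosome (0 rose and 16 fell), photosynthesis (23 rose and 0 fell), chlorophyll biosynthesis (3 rose and 10 fell), root hair formation (3 rose and 19 fell), light signalling (7 rose and 7 fell) and Polycomb (0 rose and 6 fell).

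The comparison of opened cotyledons with dry seed spans the whole transition to a photo-autotrophic seedling. The largest rises were those of RBCS1B at 8.17 ± 0.27 (adjusted p = 4.7e-16), AT3G54580 at 8.08 ± 0.16, CA1 at 7.92 ± 0.17, the chlorophyll a/b-binding protein gene CAB1 (AT1G29930) at 7.69 ± 0.25 and the germin gene GER3 (AT5G20630) at 7.67 ± 0.22. They were followed by AT2G43150 (7.57 ± 0.27), AZI1 (AT4G12470, 7.53 ± 0.16), AT3G28550 (7.51 ± 0.17), CA2 (AT5G14740, 7.45 ± 0.22) and ECS1 (AT1G31580, 7.43 ± 0.18). In dry seed 6 of these 10 genes were near the floor, with RBCS1B at 2.98 and AT3G54580 at 2.89, so these changes are lower bounds and their order is uncertain. The largest falls were those of MLP31 at -8.44 ± 0.24, AT1G14940 at -8.18 ± 0.21, SESA4 at -8.18 ± 0.33, ATPXG2 (AT5G55240) at -8.14 ± 0.25 and AT3G56350 at -8.05 ± 0.2. They were followed by ATS1 (-8.01 ± 0.25), CRU2 (-8 ± 0.35), AT1G47540 (-7.99 ± 0.25), AT1G54860 (-7.94 ± 0.28) and XTH25 (AT5G57550) (-7.88 ± 0.35), and 8 of these 10 were near the floor at OC. ATHB13 rose by 3.56 ± 0.15 (adjusted p = 1.7e-14), and its levels from DS to OC were 3.2, 2.85, 4.42, 5.68, 6.22, 6.42 and 6.76.

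All 42 photosynthesis genes rose at least 2-fold, with a median of 5.75 (adjusted p = 1.8e-21, and adjusted p = 0.038 with an estimated correlation), among them PSAK by 7.16 ± 0.18 and LHCB3 by 6.21 ± 0.16. All 15 chlorophyll biosynthesis genes rose (median 3.38, adjusted p = 2.2e-08, and adjusted p = 0.012 with an estimated correlation), GUN5 by 6.43 ± 0.19 and CRD1 by 6.32 ± 0.19. All 24 root hair genes rose (median 3.09, adjusted p = 1.6e-09, and adjusted p = 0.061 with an estimated correlation), RHS19 by 6.95 ± 0.17 and EXPA7 by 4.11 ± 0.18. Cell cycle genes rose in 32 of 35 cases and fell in 2 (median 2.08, adjusted p = 4.9e-08, and adjusted p = 0.075 with an estimated correlation). Examples were CYCD3;1 (AT4G34160) at 3.08 ± 0.17 and RNR2A at -3.66 ± 0.19. Auxin genes rose in 13 of 14 cases (median 2.81, adjusted p = 1.5e-05, and adjusted p = 0.04 with an estimated correlation), AUX1 by 5.22 ± 0.12. Expansins, XTHs and mannanases rose in 22 of 28 cases and fell in 2 (median 3.25, adjusted p = 1.5e-07, and adjusted p = 0.061 with an estimated correlation). XTH4 (AT2G06850) rose by 6.57 ± 0.21, and EXPA2, at 10.65 at 6H, had -0.44 ± 0.35 (adjusted p = 0.25).

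All genes of 5 seed lists fell. The medians were -6.22 for the 10 storage protein genes (adjusted p = 2.7e-05, and adjusted p = 0.19 with an estimated correlation), -5.86 for the 15 LEA genes (adjusted p = 1.6e-06, and adjusted p = 0.21 with an estimated correlation) and -6.92 for the 6 oil body genes (adjusted p = 0.00031, and adjusted p = 0.14 with an estimated correlation). They were -3.88 for the 14 heat shock genes (adjusted p = 4e-05, and adjusted p = 0.14 with an estimated correlation) and -3.92 for the 10 maturation and dormancy regulators (adjusted p = 1e-04, and adjusted p = 0.019 with an estimated correlation). HSFA9 fell by 6.84 ± 0.2, AHG1 fell by 7.43 ± 0.16, ABI5 fell by 5.15 ± 0.19, and DOG1 fell by 5.08 ± 0.15. Beta-oxidation genes fell in 15 of 18 cases and rose in 1 (median -1.14, adjusted p = 0.00055, and adjusted p = 0.054 with an estimated correlation). MLS fell by 2.09 ± 0.1 and ICL fell by 0.76 ± 0.09, and the gene that rose was PMDH2 (AT5G09660), for a peroxisomal malate dehydrogenase, at 4.68 ± 0.17.

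HD-Zip genes rose in 10 of 16 cases and fell in 3 (median 1.28, adjusted p = 0.012, and adjusted p = 0.069 with an estimated correlation). An example was HB-12 at 4.47 ± 0.35. Abscisic acid genes fell in 12 of 17 cases and rose in 5 (median -1.03, adjusted p = 0.25). Members included CYP707A3 at 4.01 ± 0.17 and CYP707A2 at -3.86 ± 0.25. Gibberellin genes rose in 8 of 23 cases and fell in 11 (median -0.23, adjusted p = 0.61). Examples were GA3OX1 at 3.57 ± 0.18 and GID1B at 4.64 ± 0.16. Light signalling genes rose in 12 of 21 cases and fell in 6 (median 1.07, adjusted p = 0.055), ELIP2 by 6.02 ± 0.18. Polycomb genes fell in 8 of 12 cases and rose in 2 (median -0.7, adjusted p = 0.11), RING1A at -4.22 ± 0.16 and CLF by 2.05 ± 0.16. Ribosome genes rose in 10 of 23 cases and fell in 5 (median 0.15, -0.39 on median-centred arrays, adjusted p = 0.51). Endosperm markers fell in 4 of 8 cases (median -0.42, adjusted p = 0.27), EPR1 at -5.2 ± 0.19. Seed coat markers rose in 5 of 12 cases and fell in 5 (median 0.05, -0.14 after a further quantile normalization and -0.49 on median-centred arrays, adjusted p = 0.5).

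By limma 6424 genes rose and 5992 fell at least 2-fold, 44.7% of all genes, and 9214 and 11795 did so at the adjusted p alone. On median-centred arrays 4739 rose and 10415 fell, and after a further quantile normalization 5907 rose and 6975 fell, so the split depended on the scaling. The median of all genes was -0.2, against -0.74 on median-centred arrays and -0.08 on arrays centred on reference genes. DS replicate 2 and OC replicate 2 stood apart from their groups as given above, and without both 12734 genes passed. Adjusted over the list alone, only the ribosome list differed, with 9 rises and 5 falls.

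**Figure D4:**
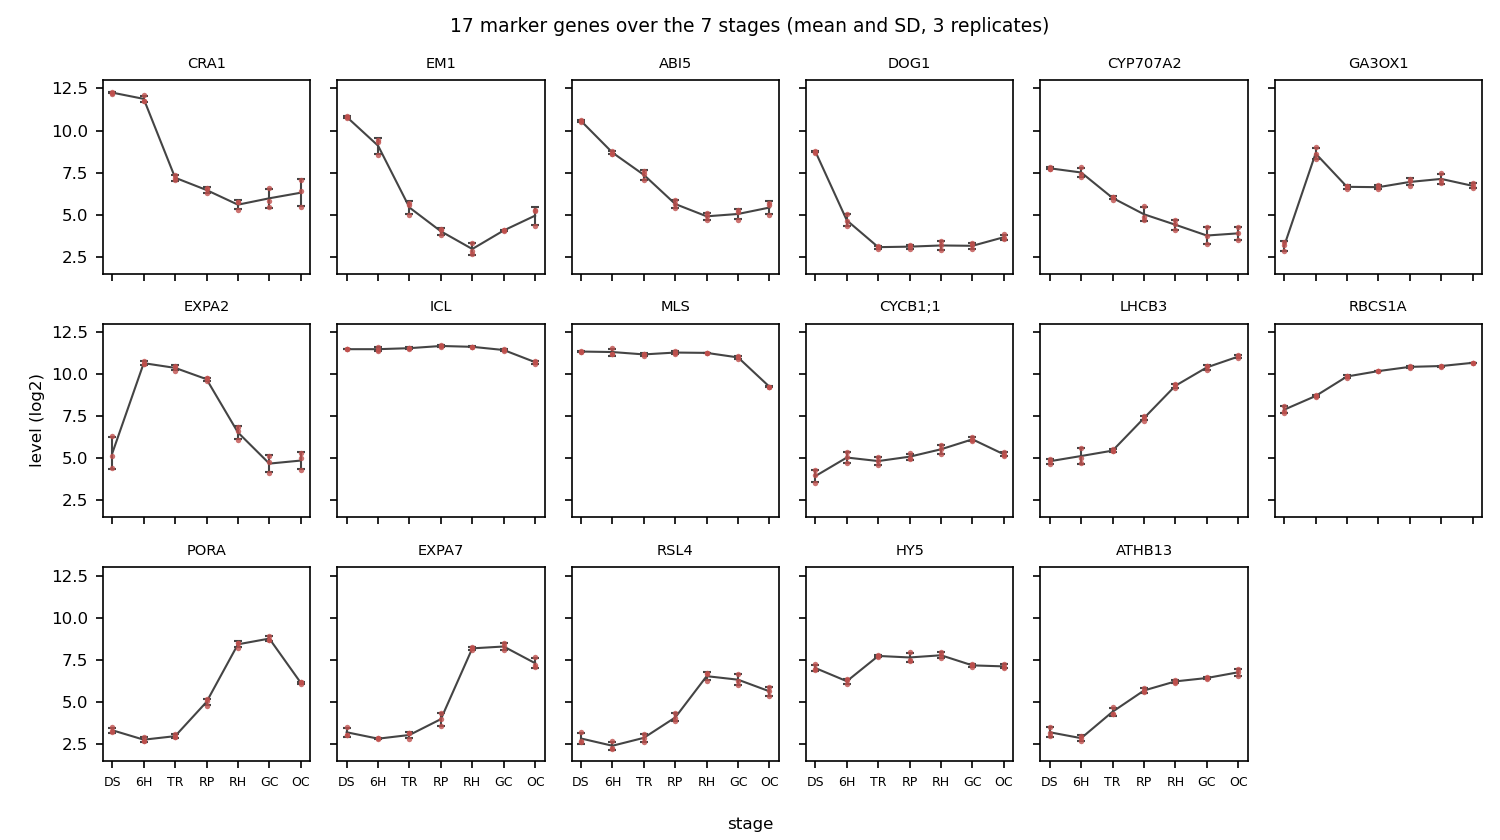
Levels (log2) of 17 genes fixed before the data were examined at the 7 stages; points are the 3 replicates, and lines and bars give the mean and SD. ICL stays between 10.71 and 11.67, EXPA2 goes from 5.31 in dry seed to 10.65 at 6H and 4.87 at OC, and PORA is highest at GC with 8.76.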

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

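Omission of DS replicate 2 and OC replicate 2 together and of genes near the floor were chosen after the data were seen, and all other alternatives were planned. No list test that passed changed its direction under any alternative applied to it. The balance of rises and falls did turn with the scaling. The counts from DS to 6H and from DS to OC are given above. Without a fold threshold falls outnumbered rises in every comparison but TR to RP, for example by 11120 to 8220 from DS to 6H. Of the 278 changes of named genes that passed, 273 kept their direction and their pass under every alternative applied to them. Treat, other fold thresholds and the fit on the 6 arrays of a comparison were applied to gene counts only. The change of ATHB13 from DS to 6H, between levels that were both near the floor, reversed, to 0.05, after a further quantile normalization, and the cause was not tested. Named changes lost their pass in 29 of 8618 values over the alternatives applied to them.

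The fold threshold moved the counts. With limma's treat against a log2 change of 1 they were 3998 from DS to 6H, 2263 to TR, 181 to RP, 512 to RH, 157 to GC and 813 to OC, and with no fold threshold 19340, 13447, 4246, 6489, 5859 and 9459, and 21009 from DS to OC. These alternatives demand more or less by construction. With a minimum range of 2, 9623 genes passed the F test, and the genes highest at each stage were 2439 at DS, 1589 at 6H, 682 at TR, 608 at RP, 692 at RH, 900 at GC and 2713 at OC. Without a minimum range 8123 genes were highest at DS.

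Centring shifted the stage of the maximum. On median-centred arrays 9970 genes were highest at DS, and on arrays centred on reference genes 2120 at 6H, 603 at RP and 6233 at OC; the cause was not tested. Distances without dim genes were 0.15, 0.109, 0.0229, 0.0437, 0.0277 and 0.0637 over the 6 steps and 0.506 from DS to OC, and by Spearman correlation 0.0189 from TR to RP and 0.342 from DS to OC; the cause was not tested.

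Of the 65 list tests that passed, 47 did not with an estimated correlation, where 18 passed, and fry, which asks another question, passed 102. Camera on ranks lost 4, median centring, dim genes left out and floor genes left out 2 each, and array weights, centring on reference genes and a replicate term 1 each. With DS replicate 2 and OC replicate 2 both left out 1 was lost, and the gene counts were 7006, 4765, 869, 1502, 998, 2380 and 12734. Omission of single arrays lost at most 1 list test, and no gene count moved by over 1.5 times.

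Replicate numbers do not pair the samples by the labels. As a pairing check, correlations of replicate-wise deviations across genes between stages ran from -0.328 to 0.124, and 4 of 21 lay above 0.1. With replicate as a block the gene counts were 7035, 4764, 862, 1496, 995, 2345 and 12417, and 64 list tests passed. Genes near the signal floor limit what can be seen: 4550 genes, 16.4%, stayed below 3.47 at every stage.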

Other observations

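The gene families and the lists of low-oxygen and water-deficit genes here were chosen after the data were seen, as were the tests for dry-seed RNA, for all 3 explanations of DS replicate 2 with the repeated choices of its genes, and for the spread of values, whereas the random groupings and the other tests were set before their result was seen. In all 14 families were tested in the 7 comparisons, 98 tests adjusted together, so the families are hypotheses. Of 94 chloroplast genome loci 92 rose from DS to OC (median 1.09, camera adjusted p = 1.2e-15, and adjusted p = 0.3 with an estimated correlation). Of 100 mitochondrial genome loci 56 rose from DS to 6H (median 0.49, 0.13 on median-centred arrays with 37 up and 29 down, adjusted p = 2.6e-06, and adjusted p = 0.38 with an estimated correlation) and 37 fell from GC to OC (adjusted p = 0.00037, and adjusted p = 0.55 with an estimated correlation). Tubulin genes rose in 13 of 15 cases from DS to OC, with a median level of 5.94 in dry seed and 8.19 at RP (adjusted p = 0.00029, and adjusted p = 0.1 with an estimated correlation). Aquaporin genes of the PIP and TIP families rose in 20 of 27 cases and fell in 5 (adjusted p = 0.00043, and adjusted p = 0.054 with an estimated correlation). Tau class glutathione transferases, enzymes of detoxification, rose in 17 of 27 cases and fell in 4 over the same span (adjusted p = 0.0021, and adjusted p = 0.1 with an estimated correlation). Nitrate and ammonium transporter genes rose in 12 of 20 cases and fell in 2 from GC to OC (adjusted p = 7.4e-06, and adjusted p = 0.039 with an estimated correlation).

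The low-oxygen list, with the alcohol dehydrogenase gene ADH1, had median levels of 6.08 in dry seed, 8.06 at TR, 7.84 at RH and 6.42 at OC. From RH to GC 12 of 25 genes fell and 2 rose (adjusted p = 0.00039, and adjusted p = 0.47 with an estimated correlation), and from GC to OC 13 fell and 3 rose (adjusted p = 0.028, and adjusted p = 0.69 with an estimated correlation). At GC its 3 replicates stood at 6.12, 6.68 and 7.68. JAZ repressor genes of jasmonate signalling fell in 8 of 10 cases from DS to 6H and rose in 2 (adjusted p = 0.016, and adjusted p = 0.32 with an estimated correlation), and rose in 8 from RH to GC (adjusted p = 4.6e-05, and adjusted p = 0.11 with an estimated correlation). From DS to OC, WRKY genes rose in 38 of 67 cases and fell in 15 (adjusted p = 0.0042, and adjusted p = 0.18 with an estimated correlation). Aux/IAA genes rose in 15 of 24 cases and fell in 7 (median 0.5, -0.03 on median-centred arrays, adjusted p = 0.054) and SAUR genes rose in 7 of 16 and fell in 2 (median 0.09, -0.44 on median-centred arrays, adjusted p = 0.52). UGT genes rose in 29 of 58 cases and fell in 22 (median 0.27, -0.27 on median-centred arrays, adjusted p = 0.34), and cytochrome P450 genes rose in 75 of 224 and fell in 72 (adjusted p = 0.32).

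Water-deficit transcripts were higher at OC than at GC, and OC replicate 2 lay below the other replicates. Of the 22 genes, of which RAB18 is also in the LEA list, 20 rose (median 1.19, camera adjusted p = 2.2e-08, and adjusted p = 0.16 with an estimated correlation), and the replicate medians at OC were 7.22, 5.88 and 7.07. Dry-seed RNA in the OC pools is argued against: 118 genes abundant in dry seed and near the floor from RP to GC had a median change of 0.25 (quartiles 0 and 0.65), where 1.23 was needed. So is a low OC replicate 2 for all risen genes: 1485 others differed there by -0.04 (quartiles -0.3 and 0.19) and the members by -0.86. A rise of all dim values stays open: members, picked with the data seen, exceeded genes of their level by 1.25 (quartiles 0.96 and 1.95). The cause stays open, and no biological explanation was tested.

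DS replicate 2 held transcripts of later stages: 34 of 36 genes abundant from TR to OC and low in DS replicates 1 and 3 were above both, with a median excess of 1.47. The choice of genes itself did not give this: with replicate 1 left out of the choice in place of replicate 2, 2 of 30 genes were highest in it (median excess -0.58), and with replicate 3 left out 0 of 25 (-0.85). Chosen by the mean of all 3, 30 of 31 genes were highest in replicate 2. RNA of opened-cotyledon seedlings is argued against by 103 genes abundant at OC and low at TR. Their median excess was 0.19 (quartiles -0.04 and 0.47) where 1.82 was needed. In these tests low at TR or at OC was a cut-off above the median level of every array. A brighter floor is argued against by an excess of 1.46 over dim genes of the same level (lower quartile 0.96). RNA of seeds at testa rupture stays open. The 14 genes abundant at TR and low at OC had a median excess of 0.86 (quartiles 0.57 and 1.49) where 1.52 was needed. This need uses the share of later-stage RNA the 36 genes imply, 3.07% (quartiles 1.51 and 5.15). No biological explanation was tested.

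Genes near the floor were lower at 6H than in dry seed: of 4550 such genes 2456 fell and 6 rose, with a median of -0.4. A different spread of values between the arrays of both stages cannot be told apart from a drop of these genes. After a further quantile normalization the median was -0.05 and 404 fell, but a median of -0.45 planted in these genes shrank to -0.17 in the same way, so that normalization takes away most of any such drop. Without DS replicate 2 the median was -0.32 and 1568 fell, so that array alone is argued against. No biological explanation was tested.

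For the 3 against 3 comparisons the 10 splits of the 6 arrays are too few for a share under 0.05. The real splits gave 7035, 4764, 863, 1497, 993, 2344 and 12416 genes in the order of the report, and the highest of the other splits gave 11, 0, 1, 1, 0, 8 and 2, so that 1 split of each 10 reached the real count. For the F test chance is excluded at this level, with 1 of 100 groupings at the real 18463 genes and 7249 in the highest other. For the list tests chance is not excluded: 24 of 100 random groupings of the arrays, the real one included, gave as many as the real 65 passing tests, and the highest other gave 85. The single list tests with the preset correlation are to be read with that limit, beside their values with an estimated correlation.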
